A study of Homo sapiens with 9 samples.

How the data were processed

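RNA sequencing was done on HKC-8, an established human kidney proximal tubular epithelial line, in 9 libraries that form 3 groups of 3. Control cells received the empty vector pcDNA3, Wnt1 cells received a plasmid for the secreted ligand Wnt1, and Wnt1_KP6 cells received the Wnt1 plasmid and KP6, a peptide derived from the anti-ageing kidney protein Klotho. Groups were taken from the treatment labels and replicate numbers from the sample titles. Every library carries the batch label 1. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was enriched on oligo(dT) beads, and libraries were made with a NEBNext Ultra kit that is not stated to keep strand, then sequenced on an Illumina NovaSeq. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

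Per the submitters' processing notes, the authors used fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM with build hg38. The role of each tool, the annotation release and any filter are not given in the sources used here. The authors deposited a table of 20323 genes with an expected count and an FPKM value for each gene and library, per the file headers. Expected counts are estimated counts that need not be whole, and 87.6% of them were whole. The deposited FPKM values are scaled by the authors to gene length and library size. An estimated count shares reads between genes with common sequence, so values of close paralogs (AKR1C1 and its relatives, the metallothioneins, MICA and MICB, CXCL3 and its relatives) and of overlapping genes are uncertain. Without strand, reads from a gene and its antisense partner cannot be told apart.

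Library totals were 21199078 to 27507623 expected counts. Levels are given as CPM (expected counts scaled to library size). A count of 0 allows up to 3 counts, or 0.109 to 0.142 CPM in a library. Such limits cover counting error only. Gene IDs were matched to GENCODE release 29 on GRCh38, the same assembly as hg38, for coordinates, gene types and exon overlaps, and 20171 of 20323 IDs matched. Chromosome, start and end are given 1-based. Genes on the Y chromosome and XIST are not reported.

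Expected counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 13153 genes. edgeR 4.0.16 in R 4.3.3 gave TMM size factors and a robust quasi-likelihood test, fitted to all 9 libraries with 3 group means and no block. All such tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Log2 fold changes are given with the standard error (SE) from that fit, and CPM as mean ± SD over 3 libraries. "Called" means past the threshold.

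The study's purpose, as its title gives it, concerns Wnt/beta-catenin and ATF3 in kidney injury and mitophagy. To fit it, 33 gene lists were fixed, and 30 with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01. Adjustment ran over the 90 tests of the 30 lists in 3 comparisons. Beside camera stand an estimated correlation per list and fry, which asks whether a list's genes move on balance in a single direction and makes no comparison with other genes. Of 1065 list entries 1061 matched a gene of the table. Members were also counted as called over all genes and as called when adjusted over the list alone. The pathway and ontology columns of the deposited table gave annotation sets of 15 to 300 tested genes, 303 from KEGG and 1466 from GO, adjusted within each.

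Groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule named WNT1, ATF3, CTNNB1 and KL in every comparison. It added the 8 called protein-coding genes with the largest change in each direction (mean CPM of at least 5, no overlap between the libraries of the 2 groups). It further allowed the 3 members of each list with the smallest p, whether or not they passed, and up to 8 genes called in opposite directions in Wnt1 vs control and Wnt1_KP6 vs Wnt1. About 30 genes per comparison were taken from these. Of the list members that the rule allows, 2 are not reported here. Any other gene is said to have been chosen after its values were seen.

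Replicate pairs were compared by a chi-square test of their counts over genes. No pair agreed within sampling noise, so no libraries were merged. Same-numbered libraries of different groups deviated together from their group means, with correlations across genes of 0.11 to 0.67 in the 9 pairs, all over 0.1. The replicate numbers taken from the titles were thus treated as pairing the samples in the fit with a replicate block. The quasi-likelihood test described above has no block and does not use this pairing. Among replicates 2 and 3 differently numbered libraries correlated at 0.15 to 0.40, about as much as same-numbered ones (0.11 to 0.41), so the pairing rests on replicate 1 against the others, and the numbers 2 and 3 are not told apart. The fit with the replicate number as a block is given where it changes the call of a named gene or list, or moves the count of genes called by over 1.5 times. Counts of list members called with the block are given for the interferon, NRF2 and ATF4 lists only, and they moved for other lists as well.

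Alternatives were RLE size factors, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 3 libraries, no count filter, a filter of 5 CPM in 3 libraries, a 2-fold threshold, the 6 libraries compared alone, a replicate block, and each library left out in turn. When a library is left out, its group keeps 2 libraries and the spread is pooled over groups. A term for replicate 1 against replicates 2 and 3 and a fit to replicates 2 and 3 only were added after seeing the data. Values given for replicate 1 alone are differences of log2 CPM (prior count 2) between 2 libraries. Fold changes and list medians given for replicates 2 and 3 come from the fit to those libraries, which has no block. The 2 are thus not quite the same measure. Comparisons that share libraries were set beside 20 simulations of unchanged groups without a replicate term. After seeing the data 20 more were run with the means and dispersions of the replicate block, so that libraries of the same number shared a shift, and 20 for replicates 2 and 3 only.

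The tests were checked on simulated counts for the same 13153 genes with 200 genes changed. In the simulation of Wnt1 vs control, 17.6% of genes changed 1.5-fold, 80.3% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, with 7 false calls. For Wnt1_KP6 vs Wnt1 the shares were 11.9%, 77.6% and 93.9% with 9 false calls, and for Wnt1_KP6 vs control 20.9%, 74.6% and 93.9% with 5 false calls. No call had the wrong direction. The changed genes were drawn from those with a mean of at least 5 CPM. Each change was the same in all 3 libraries of a group, and the libraries held no shift shared by replicate number. The shares thus do not hold for changes that differ between replicates, such as those of ATF3. A list shifted by 0.5 on the log2 scale was called in all 3 simulations and no other list was. The simulated genes varied independently, so this is no check on false list calls among correlated genes. In the data the estimated correlation ran from -0.0893 (fibroblast and endothelial markers) to 0.819 (ribosomal proteins).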

Results

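Poly(A) RNA of HKC-8 cells was sequenced in 9 libraries, 3 from cells given the empty vector (control), 3 from cells given the Wnt1 plasmid (Wnt1) and 3 from cells given the Wnt1 plasmid and the Klotho-derived peptide KP6 (Wnt1_KP6). Total expected counts were 27140742, 26726410 and 25818088 in control replicates 1, 2 and 3. They were 27507623, 21199078 and 23951742 in the libraries labelled Wnt1 and 24569560, 24429369 and 23670283 in those labelled Wnt1_KP6. Between 14915 and 15225 genes had at least 1 count, and 13153 genes were tested. Throughout, log2 fold changes stand with their SE, levels are CPM as mean ± SD of 3 libraries, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named.

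Replicate 1 stood apart from replicates 2 and 3 in all 3 groups. The first principal component held 38.1% of the variance and placed replicate 1 at -37.36 (control), -38.82 (Wnt1) and -38.33 (Wnt1_KP6), with the other 6 libraries between 9.21 and 25.07. The second component held 28.3% and ordered replicates 2 and 3 by group, from 37.67 and 38.82 in control through -7.61 and -8.11 in Wnt1 to -31.75 and -31.84 in Wnt1_KP6. Replicate 1 of the 3 groups lay between -1.57 and 2.3 on it. Wnt1 replicate 1 and Wnt1_KP6 replicate 1 differed little (chi-square per degree of freedom 3.51), about as little as replicates 2 and 3 of Wnt1 (3.15) or of Wnt1_KP6 (3.38). Control replicates 2 and 3 gave 13.9, and all other pairs gave 40.7 to 148. Mitochondrial transcripts took 5.18%, 5.26% and 5.72% of counts in replicate 1 of control, Wnt1 and Wnt1_KP6, and 7.01% to 7.97% in the other libraries.

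**Figure D1:**
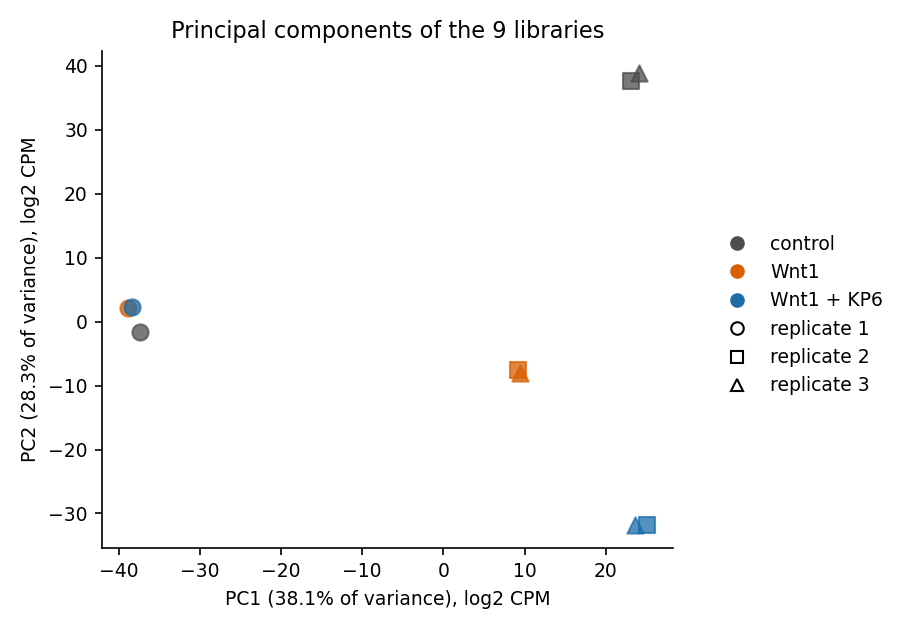
Scores of the 9 libraries on the first (38.1%) and second (28.3%) principal components of log2 CPM, 1 point per library, coloured by group and with the marker shape by replicate. Replicate 1 of every group lies near -38 on the first axis, and replicates 2 and 3 lie in pairs by group.

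The genes that the study's title and labels name come first, since the level of WNT1 bears on the labels. WNT1 (ENSG00000125084, hg38 chromosome 12, 48978453 to 48981676) had 0 counts in all 3 control libraries and 0 in all 3 libraries labelled Wnt1. The libraries labelled Wnt1_KP6 held 1, 2 and 0 counts. A count of 0 over 3 libraries allows up to 0.0376 CPM in control and 0.0413 CPM in Wnt1, which is 0.15% of the level of the median tested gene (27.5 CPM). The deposited counts thus give no check of the plasmid label, and any direction given for the plasmid rests on the labels alone. CTNNB1 (ENSG00000168036, chromosome 3, 41194741 to 41260096), which encodes beta-catenin, was at 295 ± 20.9 CPM in control and 279 ± 27.9 in the libraries labelled Wnt1. Its log2 fold change was -0.08 ± 0.10 (adjusted p = 0.847) for Wnt1 vs control, 0.07 ± 0.10 (adjusted p = 1) for Wnt1_KP6 vs Wnt1 and -0.01 ± 0.10 (adjusted p = 0.983) for Wnt1_KP6 vs control. KL (ENSG00000133116, chromosome 13, 33016433 to 33066145), which encodes Klotho, was low at 3.80 ± 0.210 CPM in control, 2.23 ± 0.694 in Wnt1 and 2.84 ± 1.11 in Wnt1_KP6. Its log2 fold changes were -0.78 ± 0.33 (adjusted p = 0.42) for Wnt1 vs control, 0.35 ± 0.33 (adjusted p = 1) for Wnt1_KP6 vs Wnt1 and -0.42 ± 0.33 (adjusted p = 0.593) for Wnt1_KP6 vs control.

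ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777), a stress-induced transcription factor, differed strongly between replicates. Its level was 18.3, 7.85 and 8.78 CPM in control replicates 1 to 3, then 30.3, 93.9 and 93.4 CPM in the libraries labelled Wnt1, then 25.4, 668.4 and 663.7 CPM in those labelled Wnt1_KP6. The log2 fold change for Wnt1 vs control was 2.64 ± 1.01 (adjusted p = 0.379), with 0.73 in replicate 1 and 3.50 ± 0.08 in replicates 2 and 3. For Wnt1_KP6 vs Wnt1 it was 2.64 ± 0.99 (adjusted p = 1), with -0.25 in replicate 1 and 2.83 ± 0.06 in replicates 2 and 3. For Wnt1_KP6 vs control it was 5.28 ± 1.13 (adjusted p = 0.0882), with 0.47 and 6.32 ± 0.08. ATF3 was thus not called by edgeR in any of the 3 comparisons over all 9 libraries, whereas DESeq2 called it in Wnt1_KP6 vs control (adjusted p = 4.79e-05). Without Wnt1_KP6 replicate 1 edgeR called it in Wnt1_KP6 vs Wnt1 (3.20, adjusted p = 0.0314) and in Wnt1_KP6 vs control (5.84, adjusted p = 0.00168). In replicates 2 and 3 alone, a setting added after seeing the data, it was called as higher in all 3 comparisons. The adjusted p was 1.7e-12 in Wnt1 vs control, 8.18e-13 in Wnt1_KP6 vs Wnt1 and 2.18e-15 in Wnt1_KP6 vs control. These p-values rest on 2 libraries per group that differed little, and measure only that spread, which may be technical.

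The comparison of Wnt1 with control asked what the plasmid label changed in tubular cells. The interferon-induced GTPase MX1 (ENSG00000157601) rose from 5.84 ± 0.933 to 18.7 ± 2.28 CPM, a log2 fold change of 1.68 ± 0.16 (adjusted p = 0.00801). The interferon-inducible IFI6 (ENSG00000126709) rose from 9.65 ± 2.40 to 31.6 ± 8.68 CPM (1.71 ± 0.24, adjusted p = 0.0475), by 0.82 in replicate 1 and 2.14 in replicates 2 and 3. KYNU (ENSG00000115919), the kynureninase of tryptophan breakdown, rose from 12.96 ± 2.42 to 38.7 ± 1.58 CPM (1.58 ± 0.14, adjusted p = 0.00801). The aldo-keto reductase AKR1C1 (ENSG00000187134) rose from 3.47 ± 0.129 to 12.2 ± 2.38 CPM (1.81 ± 0.19, adjusted p = 0.0137), a value that is uncertain because its near-identical paralogs share reads. TRIB3 (ENSG00000101255), a pseudokinase induced by the integrated stress response, rose from 106 ± 17.3 to 268 ± 0.838 CPM (1.35 ± 0.13, adjusted p = 0.00801).

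Other genes that rose were SFN (ENSG00000175793), which encodes the 14-3-3 sigma checkpoint protein (1.31 ± 0.18, adjusted p = 0.0422), the cytochrome CYP4F11 (1.31 ± 0.18, adjusted p = 0.0475) and the tetraspanin-like TM4SF19 (1.14 ± 0.13, adjusted p = 0.0203). TM4SF19 is uncertain because 42.9% of its exon bases are shared with a gene on the same strand. UGT8 (ENSG00000174607), which makes galactosylceramide, fell from 43.5 ± 1.96 to 25.3 ± 1.31 CPM, a log2 fold change of -0.78 ± 0.11 (adjusted p = 0.048). In all, 16 genes were called, 15 higher and 1 lower, and 1475 genes had an unadjusted p under 0.05, where 658 would by chance. Each of the 8 genes named as higher was also above control in replicate 1 alone, which the naming rule (no overlap between the groups) requires. DESeq2 called 302 genes, and the replicate block gave 95 (83 higher, 12 lower), both with all 16 among them. The libraries of the 2 groups did not overlap for 2175 genes (16.5%), where chance gives 10% for exchangeable libraries.

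The count depended on single libraries. Without control replicate 1 it was 885, and without control replicate 2, control replicate 3 or Wnt1 replicate 3 it was 0 with edgeR, although 729, 1583 and 892 genes had an unadjusted p under 0.05. It was 6 without Wnt1 replicate 1, 5 without Wnt1 replicate 2, 43 without Wnt1_KP6 replicate 1, 4 without Wnt1_KP6 replicate 2 and 4 without Wnt1_KP6 replicate 3.

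**Figure D2:**
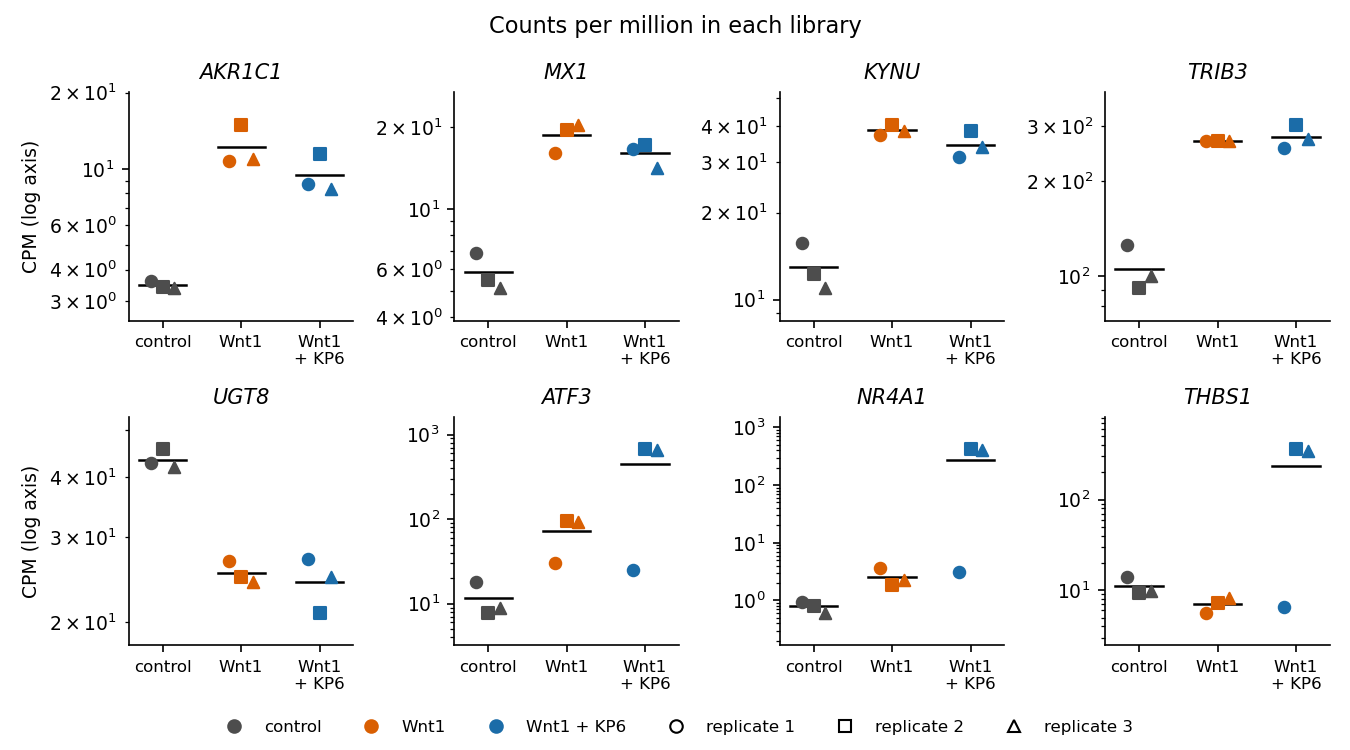
CPM on a log axis in each of the 9 libraries, with a bar at the group mean, for AKR1C1, MX1, KYNU, TRIB3, UGT8, ATF3, NR4A1 and THBS1. ATF3, NR4A1 and THBS1 are far higher in replicates 2 and 3 of Wnt1_KP6 than in replicate 1, with NR4A1 at 415.9 and 401.4 CPM against 3.15.

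Of the 30 gene lists tested, 11 were called in Wnt1 vs control at the preset correlation, 8 higher and 3 lower, and 0 with an estimated correlation (lowest adjusted p = 0.383 with an estimated correlation). The interferon-stimulated genes stood highest: the median log2 fold change over 38 members was 0.87, 36 of them lay above 0 (camera adjusted p = 2e-18), and the median was 0.84 in replicate 1 and 0.90 in replicates 2 and 3. MX1 and IFI6 were the 2 members called over all genes, and 16 were called when adjusted over the list alone. With the replicate block 17 members of this list were called over all genes. The interferon signal transducer IRF9 was at 0.60 ± 0.12 (adjusted p = 0.121), with 48.4% of its exon bases shared with another gene. The NRF2 and oxidative stress list (31 members, camera adjusted p = 2.51e-14) had a median of 0.62, with 0.28 in replicate 1 and 0.69 in replicates 2 and 3. Of its members AKR1C1 was called over all genes and 18 when adjusted over the list alone, among members with values of 2.12 ± 0.36 (OSGIN1, adjusted p = 0.0982) and 0.62 ± 0.11 (TXNRD1, adjusted p = 0.0982, and 0.0361 with the replicate block). The ATF4 and integrated stress response list (36 members, camera adjusted p = 0.00156) had a median of 0.12, with TRIB3 called over all genes and 3 members when adjusted over the list alone. Its median was 0.47 in replicate 1 and 0.02 in replicates 2 and 3, and without control replicate 1 the list was not called (camera adjusted p = 0.768). With the replicate block 6 members of the NRF2 list and 4 of the ATF4 list were called over all genes.

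Cholesterol synthesis and SREBP targets were higher in replicates 2 and 3 and not in replicate 1, and the replicates of control were the ones that differed. The median centred log2 CPM of the list was 0.22, 0.35 and 0.34 in the libraries labelled Wnt1, and 0.24, -1.28 and -1.35 in control replicates 1 to 3. Over 32 members the median was 0.83 (camera adjusted p = 4.83e-16), with -0.02 in replicate 1 and 1.78 in replicates 2 and 3. The fatty acid synthase FASN was at 0.47 and 2.29 in these (1.5 ± 0.39 over all, adjusted p = 0.217), the mevalonate enzyme MVD at 0.35 and 2.23 (1.45 ± 0.38, adjusted p = 0.221) and the lipid regulator SREBF1 at 0.79 ± 0.12 (adjusted p = 0.0663, and 0.0325 with the replicate block). No member was called over all genes, and 7 were when adjusted over the list alone. The unfolded protein response list (33 members, camera adjusted p = 3.67e-08) had medians of 0.03 and 0.46 in replicate 1 and replicates 2 and 3. Its chaperone HSPA5 was at 1.29 ± 0.24 (adjusted p = 0.11) and MANF at 0.68 ± 0.12 (adjusted p = 0.0982), and 7 members were called when adjusted over the list alone against 0 over all genes. The lysosome list (40 members, camera adjusted p = 6.36e-07) had medians of 0.10 and 0.38, with CLCN7 at 0.63 ± 0.10 (adjusted p = 0.0742, and 0.0361 with the replicate block) and MCOLN1 at 0.68 ± 0.13 (adjusted p = 0.113, and 0.0396 with the block). None of its members was called over all genes and 9 were when adjusted over the list alone.

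Inflammatory and immediate early lists were also higher. The NF-kB and cytokine list (26 members, camera adjusted p = 0.000627) had a median of 0.33 (0.17 in replicate 1 and 0.51 in replicates 2 and 3), with the cytokine CSF3 at 2.01 ± 0.31 (adjusted p = 0.0663, and 0.0444 with the replicate block) and CXCL3 at 2.33 ± 0.64 (adjusted p = 0.237). No member was called over all genes, and 3 higher and 1 lower were when adjusted over the list alone. The immediate early and AP-1 list (33 members, camera adjusted p = 0.000747) had a median of 0.73 in replicate 1 and 0.59 in replicates 2 and 3, with KLF4 at 2.39 ± 0.82 (adjusted p = 0.326) and 0 members called either over all genes or when adjusted over the list alone. Lower were the G2/M and mitosis list (44 members, median -0.19, camera adjusted p = 5.37e-08, 0 called over all genes and 1 lower when adjusted over the list alone), with CDK1 at -0.51 ± 0.10 (adjusted p = 0.121) and KIF11 at -0.39 ± 0.10 (adjusted p = 0.193). Nuclear-encoded oxidative phosphorylation (51 members, median -0.10, camera adjusted p = 0.00125) and cytosolic ribosomal proteins (47 members, median -0.06, camera adjusted p = 0.0435) were lower by little, with 0 members called over all genes or when adjusted over the list alone. In replicate 1 the medians were 0.01 (oxidative phosphorylation) and 0.08 (ribosomal) against -0.15 and -0.14 in replicates 2 and 3, and for G2/M they were -0.11 and -0.22. The ribosomal list was not called without control replicate 1 (0.401), control replicate 3 (0.163), Wnt1 replicate 2 (0.593) or Wnt1 replicate 3 (0.381).

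With an estimated correlation no list was called: adjusted p = 0.383 for the interferon, NRF2, cholesterol, unfolded protein, lysosome and G2/M lists. For the NF-kB list it was adjusted p = 0.542 with an estimated correlation, for the immediate early, ATF4 and oxidative phosphorylation lists adjusted p = 0.763 with an estimated correlation, and for the ribosomal list adjusted p = 0.922 with an estimated correlation. By fry the NRF2 list alone was called (adjusted p = 0.0283). With the replicate block the hypoxia list joined the 11 (adjusted p = 0.012 against 0.0559), but not with the block and an estimated correlation (adjusted p = 0.773). Its median was 0.72 in replicate 1 and -0.06 in replicates 2 and 3, where the direction turned to lower (adjusted p = 0.381). Camera also called the hypoxia list higher without control replicate 2 (adjusted p = 0.023), Wnt1 replicate 2 (0.0017) or Wnt1 replicate 3 (0.000977). The same held without Wnt1_KP6 replicate 1 (0.0313) or Wnt1_KP6 replicate 3 (0.0479).

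The processes that the title names were not called in Wnt1 vs control over all 9 libraries. Wnt/beta-catenin feedback and target genes (20 members) had a camera adjusted p of 0.955, a median of 0.05 and a mean of 0.00, although the test's sign was downward, and changed sign between replicate 1 (median 0.25) and replicates 2 and 3 (-0.22, adjusted p = 0.647 in these alone), with PTCH1 at -0.41 ± 0.18 (adjusted p = 0.446) and TNFRSF19 at -1.22 ± 0.71 (adjusted p = 0.574, and 0.0269 with the replicate block). Wnt pathway components had a camera adjusted p of 0.884. Mitophagy receptors and regulators (38 members) had a median of 0.02 and a camera adjusted p of 0.488, with the autophagy receptor SQSTM1 at 1.15 ± 0.18 (1114 ± 56.1 to 2466 ± 388 CPM, adjusted p = 0.0689, and 0.015 with the replicate block). The value of SQSTM1 is uncertain because 22% of its exon bases lie opposite other genes. Autophagosome genes had a camera adjusted p of 0.145, mitochondrially encoded genes 0.613 and mitochondrial biogenesis genes 0.955. Fibrosis genes (34 members, 9 above 0) had a median of -0.29 and a camera adjusted p of 0.355, with the matrix gene SPARC at -0.86 ± 0.24 (265.9 ± 98.25 to 146.7 ± 5.81 CPM, adjusted p = 0.247) and fibronectin FN1 at 0.55 ± 0.15 (5358 ± 586 to 7867 ± 935 CPM, adjusted p = 0.237, and 0.0166 with the replicate block). Proximal tubule genes were at 0.192, tubular injury genes at 0.134 and p53 targets at 0.0901. These 4 lists differed between replicates: the medians in replicate 1 and in replicates 2 and 3 were 0.24 and -0.40 for fibrosis, -0.40 and 0.45 for proximal tubule, -0.09 and 0.33 for tubular injury and -0.09 and 0.21 for p53 targets. In replicates 2 and 3 alone, the setting added after seeing the data, fibrosis was called lower (adjusted p = 4.72e-05), and proximal tubule (0.00127), tubular injury (0.000298) and p53 targets (0.000938) were called higher. Like every list call in replicates 2 and 3 alone, these are at the preset correlation, and no correlation was estimated in that setting. The other lists not called were senescence (0.464), S phase (0.125), hypoxia (0.0559), fatty acid oxidation (0.131), heat shock (0.191), apoptosis (0.216), histones (0.488), fibroblast and endothelial markers (0.49) and distal nephron markers (0.955). The renin-angiotensin list and the blood and immune cell list had 4 tested members each and the list of genes in the title 3, so they were not tested.

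**Figure D3:**
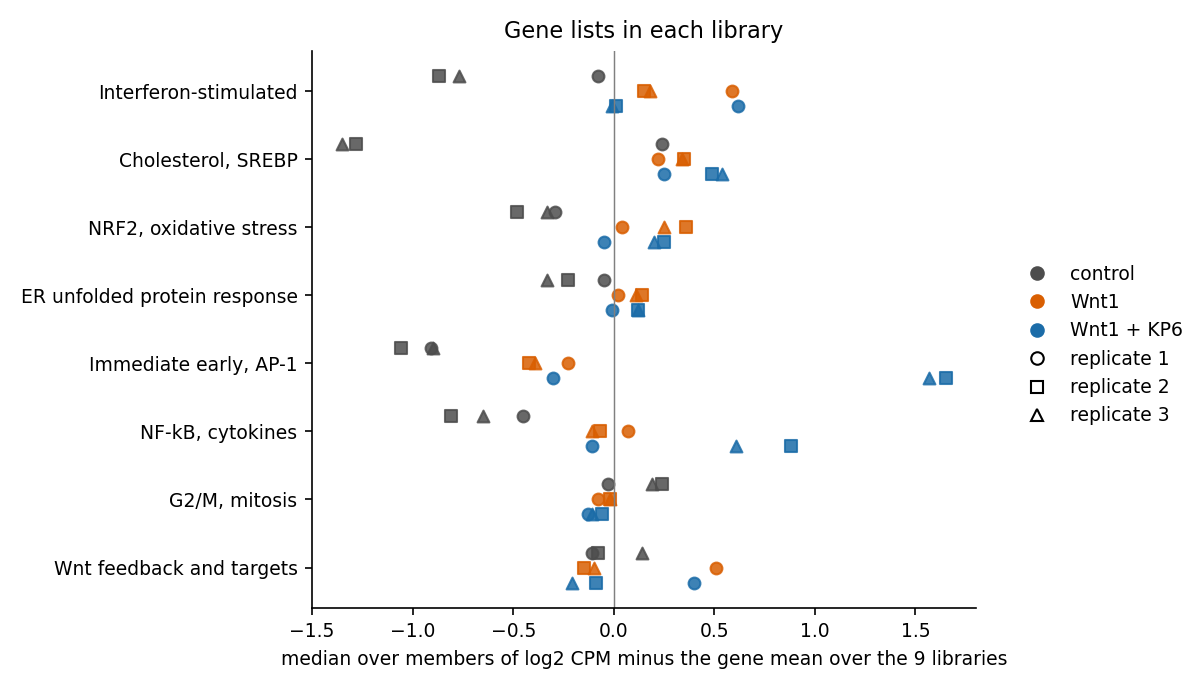
Median over the members of 8 gene lists of log2 CPM minus the gene's mean over all libraries, 1 point per library. The interferon medians lie higher in the Wnt1 and Wnt1_KP6 libraries than in control, and the immediate early medians are highest in replicates 2 and 3 of Wnt1_KP6.

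The comparison of Wnt1_KP6 with Wnt1 asked what KP6 changed in cells given the plasmid. Immediate early transcription factors were far higher in replicates 2 and 3 of Wnt1_KP6 and not in replicate 1. The nuclear receptor NR4A1 (ENSG00000123358) was at 3.62, 1.85 and 2.29 CPM in the libraries labelled Wnt1 and at 3.15, 415.9 and 401.4 CPM in those labelled Wnt1_KP6. Its log2 fold change was 6.70 ± 1.43 (adjusted p = 1), with -0.20 in replicate 1 and 7.61 ± 0.11 in replicates 2 and 3. Its relatives NR4A2 and NR4A3 were at 4.49 ± 1.04 and 6.01 ± 1.39 (adjusted p = 1 for both), with -0.33 and -0.48 in replicate 1. The matrix gene THBS1 (ENSG00000137801), which encodes thrombospondin 1, was at 5.68, 7.27 and 8.22 CPM in Wnt1 and at 6.49, 358.4 and 344.6 CPM in Wnt1_KP6 (5.07 ± 1.16, adjusted p = 1). The log2 difference of THBS1 was 0.19 in replicate 1, and its log2 fold change was 5.50 in the fit to replicates 2 and 3. Without Wnt1_KP6 replicate 1 both were called, NR4A1 with an adjusted p of 8.22e-06 and THBS1 with 1.01e-05.

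No gene was called by edgeR over all 9 libraries, and 363 genes had an unadjusted p under 0.05, where 658 would by chance. That number was 493 with the replicate block and 664 with the term for replicate 1 added after seeing the data. It thus depends on how replicate 1 is treated, and its low value is no evidence against an effect. DESeq2 called 20 genes, 18 higher and 2 lower, of which 9 were on the immediate early list, among them NR4A1 (adjusted p = 0.000345). limma-trend on FPKM called 0. Without Wnt1_KP6 replicate 1 edgeR called 211 genes, 182 higher and 29 lower. The libraries of the 2 groups did not overlap for 764 genes (5.8%), where chance gives 10% for exchangeable libraries. The shift that replicate 1 shared between the groups makes such genes rarer, so the lower share is no evidence against an effect. MT1F, a metallothionein chosen after its values were seen, was at 17.2, 24.9 and 25.7 CPM in the libraries labelled Wnt1 and at 9.76, 12.1 and 13.4 CPM in those labelled Wnt1_KP6. Its log2 fold change was -0.94 ± 0.19, with an adjusted p of 1 by edgeR and 0.0125 by DESeq2, and its reads may be shared with its paralogs.

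**Figure D4:**
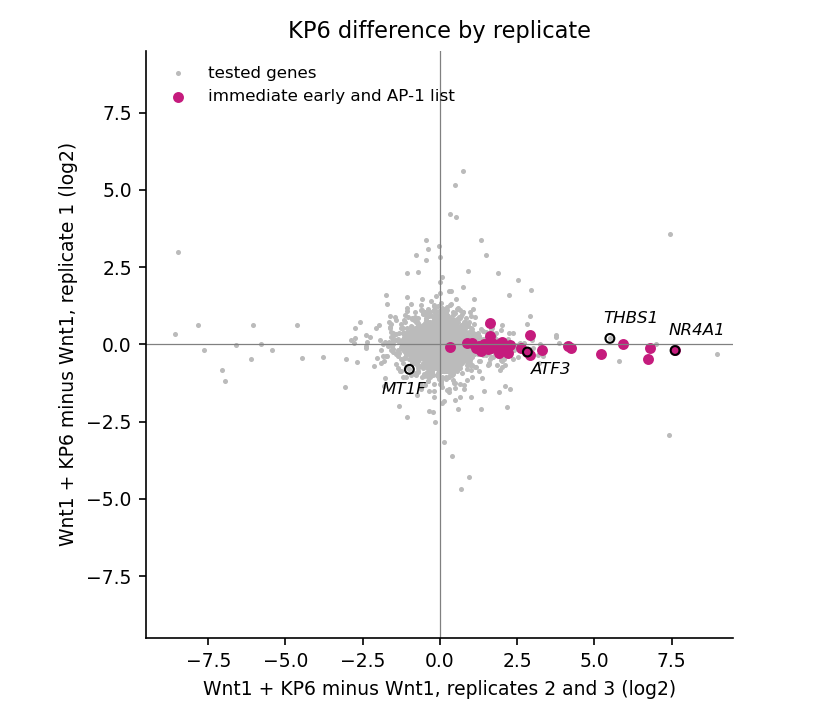
Log2 difference of Wnt1_KP6 minus Wnt1 for every tested gene, in replicates 2 and 3 (horizontal axis) and in replicate 1 (vertical axis), with the immediate early list in magenta and NR4A1, THBS1, ATF3 and MT1F circled. All 33 immediate early genes lie above 0 on the horizontal axis and 10 of them on the vertical axis.

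Among the gene lists, 8 were called in Wnt1_KP6 vs Wnt1 at the preset correlation, 6 higher and 2 lower, and 0 with an estimated correlation (lowest adjusted p = 0.383 with an estimated correlation). The immediate early list had a median of 1.43 with 33 of 33 members above 0 (camera adjusted p = 1.2e-35), and the median was -0.07 in replicate 1 and 1.95 in replicates 2 and 3. None of its members was called over all genes, and 29 were when adjusted over the list alone. The NF-kB and cytokine list had a median of 0.47 (camera adjusted p = 9.13e-13), with 0.01 in replicate 1 and 0.77 in replicates 2 and 3, and 0 members called over all genes and 4 when adjusted over the list alone. The inhibitor NFKBIA was at 1.56 ± 0.38, the adhesion molecule ICAM1 at 0.97 ± 0.28 and TNF at 2.64 ± 0.74 (adjusted p = 1 for each). Smaller shifts were called for fibrosis genes (median 0.10, camera adjusted p = 0.00189), with THBS1 and CCN2 (3.63 ± 1.21) as members, for p53 targets (0.05, 0.0022), with PLK3 at 1.83 ± 0.49 and BBC3 at 0.65 ± 0.18, and for tubular injury genes (0.13, 0.00476), with CXCL8 at 1.83 ± 0.59 and SOX9 at 1.2 ± 0.41. The senescence list (0.22, 0.0305), which also holds CXCL8, had IL6 at 1.90 ± 0.60. ICAM1 and IL6 are uncertain because 23.6% and 20.7% of their exon bases lie opposite other genes. The medians in replicate 1 and in replicates 2 and 3 were -0.04 and 0.20 for fibrosis, 0.02 and 0.05 for p53 targets, 0.00 and 0.19 for tubular injury and -0.01 and 0.37 for senescence. None of the members of these 4 lists was called over all genes or when adjusted over the list alone.

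The interferon list was lower in Wnt1_KP6 than in Wnt1 (median -0.11, camera adjusted p = 0.00382), at 0.00 in replicate 1 and -0.22 in replicates 2 and 3, with IRF9 at -0.26 ± 0.12 and STAT2 at -0.19 ± 0.10. The G2/M list was lower by little (median -0.05, camera adjusted p = 0.0128), with MKI67 at -0.23 ± 0.10 and AURKA at -0.19 ± 0.10. Both lists had 0 members called over all genes and 0 when adjusted over the list alone. The interferon list was not called without Wnt1 replicate 1 (camera adjusted p = 0.217), Wnt1_KP6 replicate 2 (0.0622) or Wnt1_KP6 replicate 3 (0.186). The G2/M list was not called without Wnt1 replicate 2 (0.0723), Wnt1 replicate 3 (0.0758) or Wnt1_KP6 replicate 1 (0.402). Without Wnt1 replicate 1 tubular injury (0.0548) and p53 (0.0978) were not called, and the senescence list was not called without Wnt1 replicate 2 (0.0729), Wnt1 replicate 3 (0.0732) or Wnt1_KP6 replicate 2 (0.0795). With an estimated correlation no list was called: adjusted p = 0.383 for the immediate early, NF-kB, p53, tubular injury and senescence lists. It was adjusted p = 0.447 with an estimated correlation for fibrosis and adjusted p = 0.763 with an estimated correlation for interferon and G2/M, and fry called 0 lists.

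Of the processes that the title names, Wnt signaling and mitophagy were not called in this comparison. Tubular injury was called at the preset correlation, but not with an estimated correlation (adjusted p = 0.383) or without Wnt1 replicate 1 (0.0548), and its median was 0.00 in replicate 1. Wnt targets had a median of 0.10 (camera adjusted p = 0.596). They were called higher with the stricter filter (0.0314) and with the term for replicate 1 added after seeing the data (0.0445), but not with the replicate block (0.0535), with an estimated correlation (adjusted p = 0.891) or with both (0.517). Among them were AMOTL2 at 0.94 ± 0.52 and MYC at 0.74 ± 0.43, and Wnt components had a camera adjusted p of 0.668. The feedback inhibitor AXIN2, chosen after its values were seen, had 66, 27 and 27 counts in control, 65, 17 and 23 in Wnt1 and 44, 7 and 4 in Wnt1_KP6. Mitophagy genes had a median of -0.01 against a mean of 0.01 (camera adjusted p = 0.955), with the kinase TBK1 at 0.20 ± 0.14. Autophagosome genes were at 0.657, lysosome genes at 0.874, oxidative phosphorylation at 0.884, mitochondrially encoded genes at 0.785, mitochondrial biogenesis at 0.946 and proximal tubule genes at 0.884. For the remaining lists the camera adjusted p was 0.884 (ATF4), 0.884 (S phase), 0.759 (unfolded protein response), 0.278 (hypoxia), 0.216 (cholesterol), 0.759 (fatty acid oxidation), 0.439 (NRF2), 0.644 (heat shock), 0.143 (apoptosis), 0.955 (ribosomal), 0.49 (histones), 0.49 (fibroblast and endothelial) and 0.439 (distal nephron). In replicates 2 and 3 alone hypoxia (0.0151) and cholesterol (0.0128) were called higher. Leaving out 1 library also gave camera calls for some of these lists, not always in 1 direction. Mitochondrially encoded genes were called lower without Wnt1 replicate 1 (adjusted p = 0.0269) and higher without Wnt1 replicate 2 (0.0205).

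The comparison of Wnt1_KP6 with control asked which differences from empty-vector cells were present with KP6. The zinc finger transcription factor KLF2 (ENSG00000127528) rose from 1.97 ± 0.238 to 10.2 ± 1.83 CPM (2.36 ± 0.33, adjusted p = 0.0383), by 2.12 in replicate 1 and 2.46 in replicates 2 and 3. BHLHE40 (ENSG00000134107), a clock-linked repressor, rose from 123 ± 8.11 to 531 ± 220 CPM (2.12 ± 0.32, adjusted p = 0.0468) and was not called with the replicate block (adjusted p = 0.0583). The laminin chain LAMB3 rose from 62.8 ± 4.97 to 157 ± 29.1 CPM (1.32 ± 0.17, adjusted p = 0.0302). MT1F (ENSG00000198417) fell from 27.9 ± 3.90 to 11.8 ± 1.83 CPM (-1.25 ± 0.19, adjusted p = 0.0468), by nearly equal amounts in replicate 1 (-1.26) and replicates 2 and 3 (-1.25). The iron exporter SLC40A1 (ENSG00000138449) fell from 30.3 ± 3.59 to 16.9 ± 1.92 CPM (-0.84 ± 0.12, adjusted p = 0.0388), and the cell cycle genes SKP2 (-0.61 ± 0.09, adjusted p = 0.0468) and ATAD5 (-0.56 ± 0.08, adjusted p = 0.0383) fell less.

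Several genes called in Wnt1 vs control were called here too. SFN rose by 1.46 ± 0.18 (adjusted p = 0.0258), MX1 by 1.46 ± 0.16 (adjusted p = 0.0195), AKR1C1 by 1.45 ± 0.19 (adjusted p = 0.0302), KYNU by 1.41 ± 0.14 (adjusted p = 0.0186) and TRIB3 by 1.39 ± 0.13 (adjusted p = 0.018), and UGT8 fell (-0.84 ± 0.11, adjusted p = 0.0303). Of the list members named by rule, CSF3 (2.58 ± 0.31, adjusted p = 0.0258), IRAK2 (0.94 ± 0.13, adjusted p = 0.0383), SQSTM1 (1.19 ± 0.18, adjusted p = 0.0468), TXNRD1 (0.71 ± 0.11, adjusted p = 0.0468) and SREBF1 (0.84 ± 0.12, adjusted p = 0.0383) rose. SQSTM1 is uncertain because 22% of its exon bases lie opposite other genes.

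In all, 30 genes were called, 25 higher and 5 lower, and 2076 had an unadjusted p under 0.05, where 658 would by chance. DESeq2 called 674 genes with all 30 among them, and the replicate block 149 with 29 of the 30. The libraries did not overlap for 2176 genes (16.5%), where chance gives 10% for exchangeable libraries. Without control replicate 1 the count was 1204, and without Wnt1_KP6 replicate 1 it was 688. It was 2 without Wnt1 replicate 2, and 0 by edgeR without control replicate 2, control replicate 3, Wnt1 replicate 3, Wnt1_KP6 replicate 2 or Wnt1_KP6 replicate 3, where 1197, 1985, 1758, 1156 and 1360 genes had an unadjusted p under 0.05.

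Among the gene lists, 14 were called in Wnt1_KP6 vs control at the preset correlation, 12 higher and 2 lower, and 0 with an estimated correlation (lowest adjusted p = 0.383 with an estimated correlation). The immediate early list had a median of 2.31 (camera adjusted p = 2.4e-20), with 0.60 in replicate 1 and 2.46 in replicates 2 and 3. KLF2 was its member called over all genes and 32 of 33 were called when adjusted over the list alone, with NR4A1 at 8.42 ± 1.59 (adjusted p = 0.0691) and the mRNA-decay factor ZFP36 at 2.90 ± 0.53 (adjusted p = 0.0691). Cholesterol genes had a median of 0.96 (camera adjusted p = 2.31e-15), with 0.01 in replicate 1 and 1.88 in replicates 2 and 3. SREBF1 was called over all genes and 10 members when adjusted over the list alone. The interferon list had a median of 0.78 (camera adjusted p = 1.5e-11), with 0.79 and 0.82 in these replicates, MX1 called over all genes and 9 members when adjusted over the list alone, and IFI6 at 1.44 ± 0.24 (adjusted p = 0.057). The NRF2 list had a median of 0.60 (camera adjusted p = 4.5e-11), with 0.26 in replicate 1 and 0.76 in replicates 2 and 3. AKR1C1 and TXNRD1 were its members called over all genes, and 18 were called when adjusted over the list alone. With the replicate block 15 members of the interferon list, 7 of the NRF2 list and 4 of the ATF4 list were called over all genes.

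The NF-kB list had a median of 0.99 (camera adjusted p = 8.91e-11), with 0.16 in replicate 1 and 1.56 in replicates 2 and 3, CSF3 and IRAK2 called over all genes, and 16 higher and 1 lower when adjusted over the list alone. The unfolded protein response list (median 0.23, camera adjusted p = 2e-07, 0 members over all genes and 10 when adjusted over the list alone) had HSPA5 at 1.35 ± 0.24 (adjusted p = 0.0584). For lysosome genes the median was 0.25 (camera adjusted p = 3.25e-05, 0 over all genes and 12 when adjusted over the list alone), with the cholesterol transporter NPC1 at 1.12 ± 0.18 (adjusted p = 0.0523, and 0.0366 with the replicate block). p53 targets (median 0.20, camera adjusted p = 0.00194, 0 over all genes and 7 when adjusted over the list alone) had TNFRSF10B at 1.09 ± 0.21 (adjusted p = 0.0691). Tubular injury genes (median 0.44, camera adjusted p = 0.00382, 0 over all genes and 4 when adjusted over the list alone) were at -0.17 in replicate 1 and 1.26 in replicates 2 and 3, with SOX9 at 1.97 ± 0.42 (adjusted p = 0.0878). ATF4 targets (median 0.10, camera adjusted p = 0.0046) had TRIB3 called over all genes and 4 members when adjusted over the list alone, and hypoxia genes (median 0.20, camera adjusted p = 0.0206) had BHLHE40 called both ways. The hypoxia list had a median of 0.65 in replicate 1 against -0.06 in replicates 2 and 3, where the direction turned to lower (adjusted p = 0.773). Apoptosis regulators had a median of 0.14 (camera adjusted p = 0.0347) and no member called over all genes or when adjusted over the list alone.

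Lower were G2/M genes (median -0.27, camera adjusted p = 8.89e-10, 0 members over all genes and 14 lower when adjusted over the list alone), with CDK1 at -0.47 ± 0.10 (adjusted p = 0.0822), and oxidative phosphorylation (median -0.09, camera adjusted p = 0.00189, 0 over all genes and 0 when adjusted over the list alone). The medians in replicate 1 and in replicates 2 and 3 were -0.02 and 0.45 for the unfolded protein response, 0.13 and 0.34 for lysosome, -0.03 and 0.46 for p53 targets, 0.32 and 0.06 for ATF4 and 0.10 and 0.18 for apoptosis. They were -0.12 and -0.35 for G2/M and 0.05 and -0.21 for oxidative phosphorylation. The ATF4 list was not called without control replicate 1 (0.792), nor was hypoxia without control replicate 1 (0.278) or Wnt1_KP6 replicate 1 (0.623). Apoptosis was not called without control replicate 3 (0.198), Wnt1_KP6 replicate 1 (0.096) or Wnt1_KP6 replicate 3 (0.0591), nor with the stricter filter (0.0905). With an estimated correlation no list was called: adjusted p = 0.383 for the immediate early, cholesterol, interferon, NRF2, NF-kB, unfolded protein, p53, tubular injury and G2/M lists. It was adjusted p = 0.447 with an estimated correlation for lysosome, 0.453 for apoptosis, 0.763 for ATF4 and oxidative phosphorylation and 0.882 for hypoxia. By fry the NRF2 and autophagosome lists were called (adjusted p = 0.0283 for both). With the replicate block senescence (0.0356), heat shock (0.0462) and ribosomal proteins (0.0171) joined the 14. With the block and an estimated correlation they were not called (camera adjusted p = 0.517, 0.517 and 0.869 in that order).

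Not called in Wnt1_KP6 vs control were Wnt targets (camera adjusted p = 0.879, with a median of 0.30 in replicate 1 and -0.17 in replicates 2 and 3), Wnt components (0.941), mitophagy genes (0.527), of which SQSTM1 was called both over all genes and when adjusted over the list alone, and autophagosome genes (0.125). Mitochondrially encoded genes were at 0.49, mitochondrial biogenesis at 0.955, fibrosis genes at 0.615, proximal tubule genes at 0.216 and senescence at 0.081. The others were S phase (0.131), fatty acid oxidation (0.123), heat shock (0.131), ribosomal proteins (0.081), histones (0.884), fibroblast and endothelial markers (0.884) and distal nephron markers (0.785). In replicates 2 and 3 alone proximal tubule (adjusted p = 0.00403, median 0.42 against -0.16 in replicate 1), senescence (0.019) and heat shock (0.0289) were called higher and ribosomal proteins (6.43e-05) lower. Some of these lists were also called with 1 library left out, such as proximal tubule without control replicate 1 (camera adjusted p = 0.00348).

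The last question was whether KP6 moved the genes called in Wnt1 vs control back toward control. For the 15 genes called higher, such as MX1 and KYNU, the return index (the Wnt1_KP6 difference from control over the Wnt1 difference from control, 1 being no return and 0 full return) was 0.95, with 0.85, 1.06 and 0.95 in the 3 Wnt1_KP6 libraries (SD 0.11). For UGT8, the gene called lower, it was 1.08 (0.87, 1.35 and 1.03, SD 0.24). With 1 Wnt1 library held out of the choice of genes and used to measure, it was 0.96 over 6 genes (Wnt1 replicate 1) and 0.86 over 5 genes (Wnt1 replicate 2). No gene was left to measure in Wnt1 replicate 3. The control libraries served for both choice and measurement, and their mean enters both differences. These values are thus no independent check. Leaving out 1 library gave 0.84 to 1.14, the highest without Wnt1_KP6 replicate 1, and no value without control replicate 2, control replicate 3 or Wnt1 replicate 3. None of these genes was called in Wnt1_KP6 vs Wnt1, where no gene at all was called, so this says nothing on a return. Without Wnt1_KP6 replicate 1, 7 of the genes called in Wnt1 vs control were also called in Wnt1_KP6 vs Wnt1, all in the same direction. The index depends on which group is control, and the WNT1 counts do not exclude an exchange of the control and Wnt1 labels. Exchanged, it is by arithmetic 1 minus the index as labelled: 0.05 (SD 0.11) for the same 15 genes and -0.08 (SD 0.24) for UGT8. The exchanged value is no second measurement.

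No gene was called in opposite directions in Wnt1 vs control and Wnt1_KP6 vs Wnt1 by edgeR, since no gene was called in the latter, and simulated unchanged groups gave 0. DESeq2 gave 1 such gene, a second identifier under the symbol CTDNEP1 (-7.15, then 6.87), chosen after its values were seen. In replicates 2 and 3 alone, a setting added after seeing the data, 253 genes were called in opposite directions, 70 up then down and 183 down then up, and 304 in the same direction. Simulated unchanged groups in this setting gave 0.7 and 0.05 on average, and independent lists 171.6 and 175.6. The simulations leave out the effects and the independent lists the shared Wnt1 libraries, so neither is a chance level for the 253. Over all 9 libraries the covariance of the fold changes over 13153 genes was -0.0157 against -0.0723 in the simulations, which share the Wnt1 libraries but hold no effect and no shift shared by libraries of the same number. With that shift taken from the replicate block, a simulation added after seeing the data, it was -0.0441, so the difference was 0.0284 in place of 0.0566. The observed value was not stable: it was -0.114 without Wnt1 replicate 1, -0.043 without Wnt1 replicate 2 and -0.0524 without Wnt1 replicate 3, and 0.00128 with the filter of 5 CPM and -0.267 with no filter. In replicates 2 and 3 alone it was -0.0396 against -0.0363 in their own simulations, within the simulated range of -0.0459 to -0.0279.

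Between Wnt1 vs control and Wnt1_KP6 vs control 13 genes were called in the same direction, 12 higher, such as AKR1C1 and TRIB3, and 1 lower (UGT8). Simulated unchanged groups gave 0 and independent lists of these sizes 0.029. The covariance of the 2 sets of fold changes was 0.137 against 0.0686 simulated, a difference of 0.0684, and against 0.0424 with the replicate shift simulated, a difference of 0.0947. It was 0.365 without control replicate 1, 0.0833 with the filter of 5 CPM, 0.435 with no filter and 0.0666 on log2(FPKM + 1). Both simulated values are for counts, the default filter and all 9 libraries. The 13 shared calls depended on the libraries too. Without control replicate 2, control replicate 3 or Wnt1 replicate 3 no gene was called in Wnt1 vs control, so none was shared. In replicates 2 and 3 alone, the setting added after seeing the data, 3270 were shared, against 0.55 simulated. Part of the shared calls may come from the shared controls, which cannot be split with 2 libraries in each part.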

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

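The term for replicate 1 against replicates 2 and 3 and the fit to replicates 2 and 3 only were chosen after seeing the data, the other alternatives before. The count of genes called moved most. For Wnt1 vs control it was 16, and it became 302 with DESeq2, 350 with the term for replicate 1 and 4115 with replicates 2 and 3 only, but 9 with the 6 libraries compared alone and 9 with a 2-fold threshold, which by construction can only lower it. For Wnt1_KP6 vs Wnt1 it was 0, against 20 with DESeq2, 1 (MT1F) with the term for replicate 1 and 1110 with replicates 2 and 3 only. For Wnt1_KP6 vs control it was 30, against 674 with DESeq2, 19 on log2(FPKM + 1), 19 on log2(FPKM + 0.1), 0 with the 6 libraries alone (1549 at an unadjusted p under 0.05), 800 with the term for replicate 1, 5272 with replicates 2 and 3 only and 14 with a 2-fold threshold. Setting replicate 1 aside lowers the spread between replicates, with a coefficient of variation of 6.04% in replicates 2 and 3 only against 21.1% over all libraries. For the other alternatives the cause was not tested.

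The replicate block, which pairs the libraries by number, gave 95 genes for Wnt1 vs control, 0 for Wnt1_KP6 vs Wnt1 (493 at an unadjusted p under 0.05) and 149 for Wnt1_KP6 vs control. Of the genes that the naming rule allows, 12 gained a call in Wnt1 vs control, among them SREBF1, TXNRD1, CLCN7, MCOLN1, SQSTM1, TNFRSF19, CSF3, FN1 and IRAK2 (adjusted p = 0.0361). In Wnt1_KP6 vs control 9 gained it, among them NPC1 (0.0366), CLCN7 (0.0344), MCOLN1 (0.0366), MYC (0.0488), MANF (0.047) and OSGIN1 (0.0471), and BHLHE40 lost it (adjusted p = 0.0583). In Wnt1_KP6 vs Wnt1 0 changed. The block also added the hypoxia list in Wnt1 vs control and 3 lists in Wnt1_KP6 vs control. None of these was called with the block and an estimated correlation (camera adjusted p = 0.773 for hypoxia, and 0.517 to 0.869 for the others).

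Leaving out 1 library gave 0 to 885 genes for Wnt1 vs control, 0 to 211 for Wnt1_KP6 vs Wnt1 and 0 to 1204 for Wnt1_KP6 vs control, with the most without replicate 1 of control or, in Wnt1_KP6 vs Wnt1, of Wnt1_KP6. The return index ranged from 0.84 to 1.14. It had no value without control replicate 2, control replicate 3 or Wnt1 replicate 3, since no gene was then called.

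Estimating the correlation per list left 0 lists in Wnt1 vs control, 0 in Wnt1_KP6 vs Wnt1 and 0 in Wnt1_KP6 vs control, against 11, 8 and 14. Fry called 1, 0 and 2 lists, of which 1, 0 and 1 were among those. The hypoxia list reversed in Wnt1_KP6 vs control with replicates 2 and 3 only (adjusted p = 0.773), and the cause was not tested. Opposite calls rose from 0 to 1 with DESeq2 and to 253 with replicates 2 and 3 only. The covariance behind them, -0.0157, ran from -0.267 with no filter to 0.00128 with the filter of 5 CPM, and the cause was not tested.

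CTNNB1, near 0 throughout, changed sign: to 0.01 on log2(FPKM + 1) and 0.01 on log2(FPKM + 0.1) for Wnt1 vs control, and to -0.09 on both for Wnt1_KP6 vs Wnt1. For Wnt1_KP6 vs control it went to 0.01 with replicates 2 and 3 only, and ranged from -0.06 to 0.04 with 1 library left out. The cause was not tested. Over all named genes the alternatives chosen before the data were examined gave 1427 values, of which 1129 kept their direction and side of the threshold, 192 lost a call, 99 gained it and 7 changed sign. Of 429 values of single called lists under the same alternatives 342 kept the call and 87 lost it. Lists not called over all 9 libraries are not in this count, and several gained a call when a library was left out. RLE size factors and the filters left all 3 gene counts within 1.5 times. Over 3 libraries 0 counts allow WNT1 up to 0.0413 CPM in those labelled Wnt1, against up to 0.142 CPM for a single library.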

Other observations

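The annotation sets, the return index and the splits of the libraries were planned, and the other tests in this part were chosen after the result was seen, as were the readings of the planned ones.

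The pathway and ontology columns of the deposited table were searched for gene sets outside the fixed lists. In Wnt1 vs control 7 KEGG pathways were called higher and 1 lower, and 19 GO processes higher and 3 lower. Ferroptosis genes (35 genes, median log2 fold change 0.17, camera adjusted p = 0.00965) and RIG-I-like receptor signaling (52 genes, 0.14, adjusted p = 0.0238) were higher. Genes of O-glycan biosynthesis other than the mucin type (35 genes, -0.19, adjusted p = 0.00457), non-motile cilium assembly (45 genes, -0.12, adjusted p = 0.0199) and centrosome duplication (17 genes, -0.17, adjusted p = 0.0393) were lower. Unadjusted p-values with an estimated correlation were 0.0342, 0.00512, 0.0333, 0.0852 and 0.12 in that order. Each of these sets had 0 members called over all genes. The annotation sets were not split by replicate in any comparison.

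In Wnt1_KP6 vs Wnt1 20 KEGG pathways were called higher and 0 lower, and 21 GO processes higher and 1 lower. Chemokine-mediated signaling (16 genes, median 0.51, adjusted p = 0.00293) and circadian rhythm (51 genes, 0.07, adjusted p = 0.0051) were higher, and embryonic skeletal system morphogenesis (40 genes, -0.10, adjusted p = 0.0389) was lower. Unadjusted p-values with an estimated correlation were 0.00879, 0.0753 and 0.175. Each of these sets had 0 members called over all genes. The NF-kB and cytokine list, which also holds chemokines, had a median of 0.01 in replicate 1 and 0.77 in replicates 2 and 3 in this comparison. In Wnt1_KP6 vs control 35 KEGG pathways were higher and 2 lower, with 47 and 3 GO processes. The lower pathways were O-glycan biosynthesis again (-0.21, adjusted p = 0.00467) and the Fanconi anemia pathway of DNA repair (52 genes, -0.13, adjusted p = 0.0146), with 0.0497 and 0.122 by an estimated correlation. Both had 0 members called over all genes.

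Replicate 1 stood apart in all 3 groups. A difference in depth does not account for it: with all libraries thinned to the smallest total, the distance of replicate 1 from the others was still at least 1.72 times that between replicates 2 and 3. Replicate 1 minus the mean of replicates 2 and 3 correlated across genes between every 2 groups, with r of 0.32 at the lowest and 0.67 between Wnt1 and Wnt1_KP6 (genes are not independent replicates). A candidate explanation is a separate round of cultures or libraries, which would give such a shared shift, though all libraries carry batch label 1. No biological explanation was tested, since the labels give none that divides replicates.

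Immediate early genes such as NR4A1 and ATF3 were higher in replicates 2 and 3 of Wnt1_KP6 and not in replicate 1. That KP6 raised them alike in all 3 replicates is argued against by the upper quartile of the 33 members' differences in replicate 1, 0.01 against a median of 1.95 in replicates 2 and 3. The differences of replicate 1 correlated with those of replicates 2 and 3 at -0.043 across genes, no more than with the differences between 2 replicates of a group (up to 0.061 in size). For genes at 5 CPM or more on average these values were -0.116 and up to 0.168. Wnt1_KP6 replicate 1 may thus come from cells that did not answer to KP6, although all 6 tested metallothioneins, such as MT1F (-0.81), were lower in it as well. Handling shortly before lysis, which induces immediate early genes, cannot be told apart from an effect of KP6 in replicates 2 and 3. The immediate early list was higher by 1.89 to 2.00 in all 4 pairs of a Wnt1_KP6 and a Wnt1 library among replicates 2 and 3, as either would give.

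The libraries labelled Wnt1 held no WNT1 counts. An exchange of the control and Wnt1 labels stays open, since the control libraries held 0 counts as well, and plasmid transcripts that were not counted would give 0 under either labelling. Low depth is argued against by the limit, which is 0.15% of the level of the median tested gene. Plasmid transcripts that were not counted as human WNT1, such as a coding sequence of another species, stay open: the 3 Wnt1_KP6 libraries held 3 counts in all, and the labels do not give the construct's sequence. A plasmid that was not expressed when RNA was taken was not tested.

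Whether KP6 returned the genes called in Wnt1 vs control toward control was tested by the return index. It was 0.95 ± 0.11 over the 3 Wnt1_KP6 libraries for genes called higher, above a bound of 0.75, set after seeing the data, by more than its SD. Each Wnt1_KP6 library was set against the means of all control and all Wnt1 libraries, not against its same-numbered ones. The SD thus holds no error of those means and may include the shift of replicate 1. With the labels as given the index for these genes as a group was near 1, the value of no return, but its full error is not known. The calls used a spread over all 9 libraries, so genes that differed between replicates, such as ATF3, were less likely to be among them. The index does not cover such genes. In replicates 2 and 3 only, a setting added after seeing the data, it was 1.02 over 2116 genes called higher. With the control and Wnt1 labels exchanged the index is by arithmetic 1 minus 0.95, or 0.05 ± 0.11, which would read as a nearly full return. It is no separate test. Since the exchange stays open, so does the return.

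Metallothioneins, zinc-binding proteins, were noticed first and then tested, so the result is a hypothesis. All 6 tested genes (MT1E, MT1F, MT1G, MT1M, MT1X and MT2A) were lower in Wnt1_KP6 than in Wnt1 in all 3 same-numbered pairs, as were 14.2% of all genes. MT1F was at -0.81, -1.03 and -0.94, MT1G at -0.87, -1.55 and -0.97 and MT2A at -0.34, -0.31 and -0.40. With a term for replicate 1, added after seeing the data, MT1F was the only gene called (-0.93 ± 0.09, adjusted p = 0.04). With the replicate block no gene was called. KP6 may lower metallothionein transcripts in all 3 replicates, but these genes share reads and regulators, so the 6 are not independent.

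Other splits of the 6 libraries in each comparison were fitted in the same way. In Wnt1 vs control 16 genes were called and the highest other split gave 0, so 1 of 10 splits gave as many. In Wnt1_KP6 vs Wnt1 the real split and the highest other gave 0, so all 10 did, and in Wnt1_KP6 vs control 30 were called against 0 in the highest other, so 1 of 10 did. With 10 splits the share cannot go under 0.1, which is too few for a share under 0.05.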
